A study of Homo sapiens with 8 samples.

How the data were processed

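Human HEK293T cells, an embryonic kidney line that carries the SV40 large T antigen, expressed the translation initiation factor subunit eIF3d with an HA tag and a cleavage site for TEV protease. Per the labels' protocols, cells spent 48 h in complete medium (DMEM with 10% fetal bovine serum) or in medium lacking glucose with dialyzed serum at the same share. RNA was crosslinked to protein with ultraviolet light of 254 nm, eIF3d was captured on anti-HA beads, and TEV protease set it free from the rest of eIF3. Per the labels, libraries were made from polyadenylated RNA of the eIF3d immunoprecipitate (IP) and of the input. There were 4 groups, the input and the IP in each medium, with 2 libraries each. The labels number the replicates without saying that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No IP from cells without the tag was analysed here, so binding to beads or to tube walls has no background value.

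Expression values were deposited as RPKM, reads scaled to exon length and to the library's reads, in 2 tables, 1 per medium. Per the submitters' processing notes, cutadapt, HISAT2 and SAMtools were used with the genome build GRCh38. Their versions, the read counter, the annotation, the use of strand and the treatment of reads with several places in the genome are not given in the sources used here. The tables listed 57998 and 57978 genes, and the 57978 present in both were used. A few identifiers stood under more than 1 symbol, 3 in the complete table and 4 in the glucose-free table, and were used 1 time each.

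The low values were searched for whole reads. Exon lengths of GENCODE release 29 turned 97.5% to 98.0% of low values per library into whole reads within 0.02, over values of up to 50 reads, and 98.6% of genes came out whole in all 8 libraries. Library totals recovered this way were 31708992 and 19490709 reads for the complete inputs, 24596452 and 21216042 for the complete IPs, 33996875 and 43400888 for the glucose-free inputs, and 8656923 and 12034189 for the glucose-free IPs. A floor of 3 reads equals 0.0691 to 0.346 RPM, the same unit without the length. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

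Genes with a mean RPKM of at least 1 over the 8 libraries were tested, 10100 in all, of which 8318 were nuclear protein-coding genes. The design was fixed before the data were examined. Values were log2(RPKM + 1), centred on each library's median over the tested genes, and limma 3.58.1 in R 4.3.3 fitted the 4 groups in 1 model with an intensity trend in the prior variance. The 4 comparisons were IP against input in each medium, the difference of these IP to input ratios between media (glucose-free minus complete), and input in glucose-free against complete medium. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale and understate the change of low genes. Centring took out a median shift of 1.21 (log2) in the complete IP against input, 1.92 in the glucose-free IP against input, 0.71 in the ratio difference and -0.41 between the inputs, and all changes are relative to it. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so single genes rest on the limma model.

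The fit was tested on simulated reads with 200 genes changed 2-, 4- or 8-fold among 10100. In the complete IP against input it recovered 68.5%, 99.5% and 100% of them. It also called 14.8% to 15.5% of the unchanged genes in that comparison and 32.4% to 33.2% in the glucose-free IP against input, because centring after the log shifts low genes. In the ratio difference it recovered 0%, 78.5% and 96.5% and called at most 15 unchanged genes. A second fit was therefore added after the data and this outcome were seen: each library's RPKM was scaled to one median before the pseudocount. It recovered 7.5%, 95.5% and 99.5% in the complete IP against input and called 0.0202% to 0.586% of the unchanged genes there, and 0 in the glucose-free IP against input. In the ratio difference it recovered 0%, 64.5% and 93.5%. Simulated genes shared 1 dispersion per group (0.0641 and 0.0569 in the complete input and IP, 0.005 without glucose), so real error rates may be higher. The centred fit stayed the main one, as fixed. Counts are given for each fit and for genes past the threshold in both with the same direction. Single genes are called higher or lower without remark only where both fits passed.

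Gene lists, part of that design, were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the residuals, and with fry. The 23 lists with at least 5 tested members covered eIF3 subunits, other translation initiation and elongation factors, cytosolic and mitochondrial ribosomal proteins, the mTOR pathway, AMPK and glucose-sensing regulators, the integrated stress response, endoplasmic reticulum chaperones, glycolysis, gluconeogenesis, the TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cholesterol synthesis, heat shock proteins, immediate early genes, DNA replication and cell cycle, replication-dependent histones, lysosome and autophagy, long noncoding RNAs, small nucleolar RNAs, ZNF zinc finger proteins, and RNA-binding proteins of stress granules and P-bodies. On simulated data camera found the raised list under both correlations and called 0 of 20 unchanged lists. The simulated genes were drawn independently, so this did not test lists whose members move together. In the real data the estimated correlation reached 0.624 for cytosolic ribosomal proteins and 0.987 for mitochondrially encoded mRNAs. Casein kinase 2 genes were too few for a test, and 25 markers of other cell types were looked up in each library. Named genes followed a fixed rule: per comparison, the 8 largest rises and 8 largest falls among genes with a symbol, a mean RPKM of at least 5, an adjusted p under 0.05 and the same direction in all pairs of libraries, plus 8 focus genes and, per called list, the 2 highest and 2 lowest members past the threshold. Genes outside this rule that are named were chosen after their values were seen. A few genes, 1 of them with a sign that turned in an alternative, are not reported here.

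The alternatives set beforehand were RPKM without centring, quantile normalization, a pseudocount of 0.1, no filter, a mean RPKM of at least 5, no intensity trend, a fold threshold, only the libraries compared, the IP libraries alone, a replicate block, and each library left out in turn. Added after the data were seen were the scaled fit with the same leave-outs and block, voom weights on the recovered reads, protein-coding genes only, removal of each library's trend on exon length, coding length and GC content with splines of 5 degrees of freedom, an earlier form of that removal without coding length, and the gene lists with each library left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.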

Results

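The series asked which mRNAs were bound by eIF3d, the eIF3 subunit that can hold the cap of some mRNAs, in fed cells and in cells kept without glucose, and whether that binding differed between these states. The 4 groups of 2 libraries held 8656923 to 43400888 reads each. Replicates of a group correlated across genes with r = 0.959 in the complete inputs, 0.896 in the complete IPs, 0.994 in the glucose-free inputs and 0.983 in the glucose-free IPs.

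The make-up of the libraries differed between IP and input and between media. Nuclear protein-coding genes took 28.7% ± 0.516 of reads in the complete inputs and 54.4% ± 0.936 in the complete IPs (SD, n = 2), and 28.2% ± 1.13 and 61.2% ± 5.34 in the glucose-free inputs and IPs. The 2 mitochondrial rRNAs took 33.1% ± 8.90 and 5.94% ± 6.61 in complete medium, and 50.01% ± 0.912 and 0.506% ± 0.151 without glucose. Complete IP replicate 2 stood apart with 10.6% mitochondrial rRNA against 1.26% in replicate 1. Another 26.8%, 34.8%, 14.6% and 34.3% of reads in these 4 groups lay on 4 noncoding genes of chromosome 21 placed on the opposite strand of 18S rRNA copies, whose reads cannot be told from rRNA without strand. Of 25 markers of other cell types at most 4 reached 1 RPKM in a library, the highest being HBA1 at 10.0 RPKM in complete input replicate 1.

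**Figure D1:**
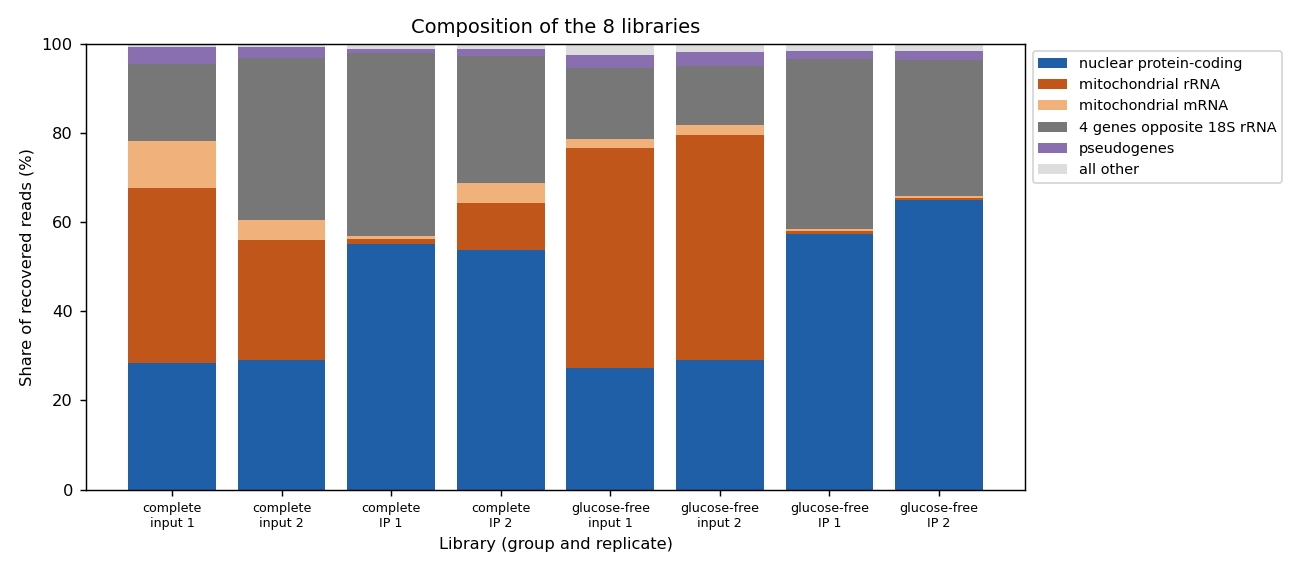
Share of recovered reads (%) per gene class in each of the 8 libraries, stacked to 100%. Mitochondrial rRNA is the largest class in both glucose-free inputs (mean 50.01%) and takes 10.6% of complete IP replicate 2 against 1.26% of complete IP replicate 1.

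The first comparison asked which mRNAs were over- or under-represented with eIF3d in fed cells. JUN, a transcription factor gene whose mRNA is a known cap target of eIF3d, had 8.60 ± 4.84 RPKM in the input and 240.0 ± 11.3 in the IP (SD, n = 2), a log2 change of 3.54 ± 0.34 (SE, limma adjusted p = 9.56e-05). LARP1, an RNA-binding regulator of ribosomal protein mRNAs, went from 11.1 ± 5.11 to 166 ± 21.2 RPKM (2.64 ± 0.29), and RPTOR, the mTORC1 scaffold, from 2.53 ± 1.77 to 32.9 ± 5.19 (2.14 ± 0.27). Ribosomal protein mRNAs lay at the other end: RPS21 fell from 1010.4 ± 416 to 21.1 ± 4.80 RPKM (-6.67 ± 0.46). The IP values have no background from cells without the tag.

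The focus genes were read on GRCh38 with GENCODE release 29, over all exons of each gene: JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327, minus strand), LARP1 (ENSG00000155506, chromosome 5, 154712902 to 154817607, plus strand), RPTOR (ENSG00000141564, chromosome 17, 80544819 to 80966371, plus strand), EIF3D (ENSG00000100353, chromosome 22, 36510850 to 36529436, minus strand), MTOR (ENSG00000198793, chromosome 1, 11106535 to 11262507, minus strand), ATF4 (ENSG00000128272, chromosome 22, 39519695 to 39522685, plus strand), EIF2AK4 (ENSG00000128829, chromosome 15, 39934146 to 40035591, plus strand) and BTG1 (ENSG00000133639, chromosome 12, 92140278 to 92145897, minus strand). In complete medium EIF3D, the gene of the tagged protein, rose in the IP by 1.36 ± 0.32 and MTOR by 1.63 ± 0.33. After each library's trends on length and GC were removed, MTOR turned to -0.11, LARP1 stood at 1.40, RPTOR at 1.11 and JUN at 3.48. Reads of the EIF3D transgene and of the cell's own gene are not separated here. ATF4, a stress-response transcription factor, had 102 ± 17.8 and 284 ± 2.60 RPKM and a log2 change of 0.27 ± 0.36 (limma adjusted p = 0.546). EIF2AK4, the amino acid sensor GCN2, had 0.34 ± 0.17 (adjusted p = 0.124) and BTG1 -0.20 ± 0.22 (adjusted p = 0.472), both at low RPKM and neither past the threshold. Alternatives called these 3 genes. With RPKM as deposited ATF4 (1.48, adjusted p = 0.00441), EIF2AK4 (1.54, 8.95e-05) and BTG1 (1.01, 0.00293) passed as higher. ATF4 also passed with quantile normalization (2.69, adjusted p = 0.000175). After the trends were removed EIF2AK4 passed as lower (-0.86, adjusted p = 0.00109) and BTG1 as higher (0.87, adjusted p = 0.0288). EIF3D then missed the threshold (0.67, adjusted p = 0.0516), as it did when only the libraries compared were fitted (1.36, adjusted p = 0.103).

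**Figure D2:**
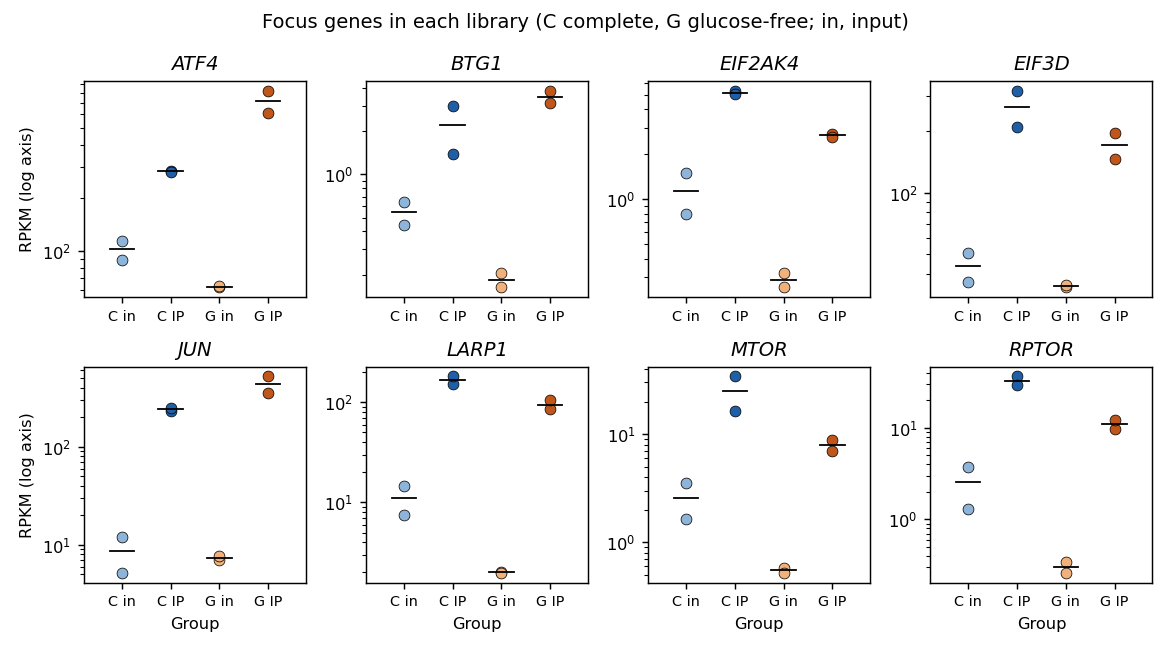
RPKM on a log axis of the 8 focus genes in each library, as points, with the mean of each group of 2 libraries as a bar. JUN means are 8.60 and 240.0 RPKM in the complete input and IP and 7.31 and 439 in the glucose-free input and IP.

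The largest rises in complete medium, beside JUN, were SPEN, a transcriptional repressor, at 4.28 ± 0.49, SPTBN1, a spectrin of the membrane skeleton, from 1.07 ± 0.156 to 76.8 ± 21.2 RPKM, the histone methyltransferase gene KMT2D at 3.89 ± 0.31, PRRC2B at 3.76 ± 0.39, the cytolinker gene PLEC at 3.72 ± 0.25, ANKRD11 at 3.45 ± 0.23 and PPP1R9B at 3.39 ± 0.24. Among the largest falls, BCYRN1, a short RNA polymerase III transcript, fell from 13831 to 50.7 RPKM (-9.42 ± 0.56), as did SCARNA22 (-7.99 ± 0.27), the mitochondrial tRNA MT-TS1 (-7.85 ± 0.82) and SNHG25 (-7.26 ± 0.46). RPS10 (-6.65 ± 0.32) and RPS27 (-6.56 ± 0.51) fell with RPS21. The pseudogene RPS15AP17 was listed at 0 in both complete IP libraries and at 52.5 RPKM in the input, and reads of such copies are uncertain.

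Of the fixed lists, the cytosolic ribosomal protein list moved most: 78 of 79 genes fell (79 adjusted over the list alone, 78 in both fits), with a median of -4.58 (camera adjusted p = 8.80e-23, and adjusted p = 0.725 with an estimated correlation). RPL4 fell least among the named members (-1.97 ± 0.32) and turned to 0.13 with quantile normalization. In the mitochondrial ribosomal protein list 67 of 72 fell (68 adjusted over the list alone, 66 in both fits; camera adjusted p = 1.33e-16, and adjusted p = 0.502 with an estimated correlation), among them MRPL41 at -4.71 and MRPL52 at -4.53. Nuclear-encoded oxidative phosphorylation fell in 64 of 68 (65 adjusted over the list alone, 63 in both fits; camera adjusted p = 1.15e-17, and adjusted p = 0.684 with an estimated correlation), with ATP5ME at -6.02 and NDUFA1 at -5.40, parts of ATP synthase and complex I. The TCA cycle list fell in 15 of 24 (15 adjusted over the list alone, 12 in both fits; camera adjusted p = 0.0128, and adjusted p = 0.74 with an estimated correlation), with SDHB at -3.25 and SUCLG1 at -2.38. Without complete input replicate 2 that list did not pass (adjusted p = 0.127). Mitochondrially encoded mRNAs fell in 8 of 13 (8 adjusted over the list alone, 8 in both fits; camera adjusted p = 0.0453, and adjusted p = 0.956 with an estimated correlation), with MT-CO3 at -5.57 and MT-ATP8 at -4.74. Beside this list, complete IP replicate 2 held 4.52% mitochondrial mRNA and replicate 1 0.565%. The list did not pass without complete input replicate 1 or without complete IP replicate 1, with adjusted p of up to 0.408.

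Immediate early genes rose in 12 of 26 (12 adjusted over the list alone, 12 in both fits; camera adjusted p = 0.00164, and adjusted p = 0.74 with an estimated correlation), led by JUN and MYC (1.68). The list did not pass without complete IP replicate 1 (adjusted p = 0.232). RNA-binding proteins of stress granules and P-bodies rose in 11 of 25 (9 adjusted over the list alone, 10 in both fits; camera adjusted p = 0.000485, and adjusted p = 0.74 with an estimated correlation), with CNOT1, the scaffold of the deadenylase complex, at 2.09 and TNRC6B, a partner of Argonaute, at 1.69. After length and GC trends were removed their median turned to -0.081 and the list no longer passed (adjusted p = 0.956), nor did CNOT1 (0.29) and TNRC6B (0.21). ZNF genes went both ways, 67 higher and 17 lower of 175 (63 and 15 adjusted over the list alone, 64 and 13 in both fits), and the list passed upward (camera adjusted p = 0.000123, and adjusted p = 0.684 with an estimated correlation). ZNF146 rose by 2.71 and ZNF276 by 2.48, and ZNF581 fell (-2.52). Small nucleolar RNAs fell in 24 and rose in 2 of 43 (25 and 2 adjusted over the list alone, 14 and 1 in both fits; camera adjusted p = 0.00343, and adjusted p = 0.74 with an estimated correlation). SNORA11F (-5.68) and SNORA80B (-5.08) fell, and SNORD62B rose (1.18). Histones did not pass as a list (adjusted p = 0.947), and their median of -0.10 and their test had opposite signs. After length and GC trends were removed the list passed upward (median 1.62, camera adjusted p = 0.000719, and 0.451 with an estimated correlation). The scaled fit had a median of -0.58 (adjusted p = 0.172), so its direction rests on that choice.

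In all, 2417 genes were higher and 3315 lower in the complete IP in the centred fit and 3033 and 3044 in the scaled fit. In both fits 2198 were higher and 2854 lower, of which 1965 and 2098 were nuclear protein-coding. Higher genes made up 42.2% of calls with centring, 49.9% with scaling and 83.8% with RPKM as deposited (6426 higher and 1245 lower). Quantile normalization gave 54.5%. On simulated data the centred fit called 14.8% to 15.5% of unchanged genes, which limits what its counts show. The IP to input ratio rose with exon length across coding genes (r = 0.503), which are not independent replicates.

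The same comparison was made in cells kept without glucose. MYH9, the heavy chain of nonmuscle myosin IIA, went from 1.77 ± 0.00375 RPKM in the input to 775 ± 516 in the IP (SD, n = 2), a log2 change of 6.03 ± 0.56 (limma adjusted p = 0.000147). DBN1, ACTN4 and PPP1R9B, genes of actin-binding proteins, rose by 4.92 ± 0.48, 4.70 ± 0.45 and 5.22 ± 0.24, and MYH10, another nonmuscle myosin, by 4.43 ± 0.54. JUN rose from 7.31 ± 0.510 to 439 ± 116 RPKM (3.79 ± 0.34, limma adjusted p = 0.000142). The mitochondrial rRNAs MT-RNR2 (-8.79 ± 1.08) and MT-RNR1 (-8.18 ± 0.85) fell, and they took 50.01% of reads in the inputs.

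PRRC2B (5.10 ± 0.39), PLEC (4.64 ± 0.25) and FBXL19 (4.46 ± 0.32) also rose. Among the falls, MTRNR2L12, MTRNR2L8 and MTRNR2L2 are nuclear copies of MT-RNR2 (-8.81, -8.65 and -8.11) and their reads are uncertain. BCYRN1 (-7.49 ± 0.56) and the tRNA MT-TC (-7.65 ± 0.54) fell too. MT-TA was listed at 0 in both glucose-free IP libraries, against 44.1 RPKM in the input. LARP1 rose from 1.995 ± 0.0244 to 95.1 ± 14.2 RPKM (3.08 ± 0.29) and RPTOR from 0.299 ± 0.0553 to 10.95 ± 1.76 (1.28 ± 0.27). ATF4 had 62.6 ± 0.776 and 715 ± 145 RPKM, with 1.56 ± 0.36 in the centred fit (limma adjusted p = 0.00714) and an adjusted p of 0.168 in the scaled fit. Without glucose-free input replicate 1, glucose-free input replicate 2 or glucose-free IP replicate 2, ATF4 did not pass (adjusted p of up to 0.0676). EIF3D (0.34 ± 0.32, adjusted p = 0.392), MTOR (0.60 ± 0.33, 0.157), EIF2AK4 (-0.41 ± 0.17, 0.072) and BTG1 (-0.0016 ± 0.22, 0.996) did not pass, though BTG1 turned to a rise in the scaled fit (0.76, adjusted p = 0.0117) and after the trends were removed (1.62, 0.00123). With RPKM as deposited these 4 passed as higher: EIF3D (2.26, adjusted p = 0.000196), MTOR (2.52, 5.13e-05), EIF2AK4 (1.51, 7.30e-05) and BTG1 (1.92, 2.03e-05). After the trends were removed EIF3D (-0.68, adjusted p = 0.0483) and EIF2AK4 (-0.53, 0.013) passed as lower.

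Without glucose, 78 of 79 cytosolic ribosomal protein genes fell in the IP (78 adjusted over the list alone, 78 in both fits), with a median of -3.48 (camera adjusted p = 1.49e-16, and adjusted p = 0.733 with an estimated correlation). RPL39 (-5.56) and RPS21 (-5.04) fell most. Mitochondrial ribosomal proteins fell in 66 of 72 (66 adjusted over the list alone, 65 in both fits; camera adjusted p = 1.25e-11, and adjusted p = 0.733 with an estimated correlation), with MRPL41 at -3.35 and MRPS18C at -3.25. Oxidative phosphorylation fell in 64 of 68 (67 adjusted over the list alone, 64 in both fits; camera adjusted p = 2.00e-12, and adjusted p = 0.733 with an estimated correlation), with NDUFB11 at -3.69 and NDUFA4 at -3.66. The TCA cycle fell in 15 of 24 (15 adjusted over the list alone, 15 in both fits; camera adjusted p = 0.00665, and adjusted p = 0.733 with an estimated correlation), with SDHB at -2.72 and IDH3G at -2.28. Mitochondrially encoded mRNAs fell in 10 of 13 (12 adjusted over the list alone, 10 in both fits; camera adjusted p = 0.0235, and adjusted p = 0.823 with an estimated correlation), with MT-CO2 at -5.72 and MT-CO3 at -5.23. Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, fell in 15 of 17 (17 adjusted over the list alone, 15 in both fits; camera adjusted p = 0.000578, and adjusted p = 0.733 with an estimated correlation), with HIST1H4C at -3.30 and HIST1H4H at -2.84. After length and GC trends were removed the histone median was -0.47, in place of -2.69 in the scaled fit, and the list did not pass (adjusted p = 0.161). Small nucleolar RNAs fell in 40 of 43 (41 adjusted over the list alone, 38 in both fits; camera adjusted p = 1.15e-08, and adjusted p = 0.733 with an estimated correlation). SNORD41 was listed at 0 in both glucose-free IP libraries against 15.1 RPKM in the input, and SNORD46 fell from 17.3 to 2.62 RPKM.

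The integrated stress response list held 10 higher and 3 lower of 35 (9 and 3 adjusted over the list alone, 7 and 2 in both fits; camera adjusted p = 0.00812, and adjusted p = 0.823 with an estimated correlation). SLC7A5, an amino acid transporter, rose by 3.60 ± 0.47 and PPP1R15A, which directs dephosphorylation of eIF2α, by 3.23 ± 0.33. In the scaled fit the list did not pass (adjusted p = 0.835) and its median was -0.098 in place of 0.17. Immediate early genes held 10 higher and 3 lower of 26 (10 and 3 adjusted over the list alone, 9 and 0 in both fits; camera adjusted p = 0.0235, and adjusted p = 0.823 with an estimated correlation), with JUND at 3.26. That list did not pass without complete IP replicate 1 or complete IP replicate 2 (adjusted p of up to 0.0942). ZNF genes held 47 higher and 35 lower of 175 (44 and 34 adjusted over the list alone, 43 and 12 in both fits), and the list passed upward (camera adjusted p = 0.0129, and adjusted p = 0.733 with an estimated correlation) although its median was -0.052 and its mean 0.14. ZNF703 (3.80) and ZNF865 (3.18) rose, and ZNF581 (-2.02) and ZNF239 (-1.62) fell, though ZNF239 stood at 0.30 with RPKM as deposited and 0.19 with no filter. Stress granule and P-body proteins did not pass (adjusted p = 0.276).

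In all, 1812 genes were higher and 3736 lower in the glucose-free IP with centring, 2825 and 3240 with scaling, and 1534 and 2685 in both, while 115 passed in opposite directions. Higher genes made up 32.7% of calls with centring, 46.6% with scaling and 93.7% with RPKM as deposited (8250 and 554), and 49.8% with quantile normalization and 46.3% with voom. On simulated data the centred fit called 32.4% to 33.2% of unchanged genes. Counts also moved in fits that left out 1 library, which still shared 1 spread per gene over the groups.

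The IP to input ratios of both media, which share no library, correlated across genes with r = 0.768 and rho = 0.713, and with r = 0.833 and rho = 0.816 in the scaled fit. Genes are not independent replicates, so no p is given. Genes higher in both IPs numbered 1198, against 434 from independent lists, and genes lower in both 2452, against 1226. Both lists came from 1 fit that shares each gene's spread, and centring shifted low genes in both IPs. The overlap can therefore exceed the independent number without shared binding. The scaled fit gave 1985 against 848 and 2489 against 976, with 24 genes in opposite directions in place of 237. JUN, LARP1, RPTOR, PLEC, PRRC2B and PPP1R9B were among those higher in both, and RPS21, MRPL41, SDHB and MT-CO3 among those lower in both.

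**Figure D3:**
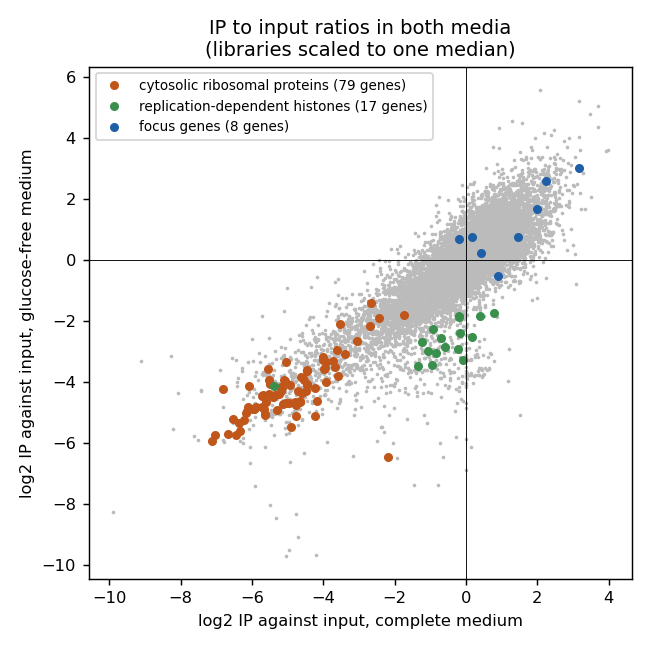
Log2 IP to input ratio of each of the 10100 tested genes in complete (x axis) and glucose-free medium (y axis), with libraries scaled to one median before the log; coloured points are 79 cytosolic ribosomal protein, 17 histone and 8 focus genes. Ratios in both media correlate with r = 0.833, ribosomal protein genes lie low in both, and most histone genes lie lower without glucose.

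The third comparison tested whether the IP to input ratio itself differed between media, by an interaction term. None of the 8 focus genes passed it: JUN had a difference of 0.24 ± 0.49 (limma adjusted p = 0.744), LARP1 0.44 ± 0.42, RPTOR -0.87 ± 0.38, MTOR -1.03 ± 0.47, EIF3D -1.02 ± 0.46, ATF4 1.29 ± 0.51, EIF2AK4 -0.74 ± 0.24 and BTG1 0.20 ± 0.32, with adjusted p from 0.0712 to 0.744. Between the IP libraries alone, without the inputs, EIF2AK4 (-1.05, adjusted p = 0.00194), RPTOR (-1.80, 0.0014), MTOR (-1.78, 0.00348), LARP1 (-1.10, 0.0157) and EIF3D (-0.91, 0.0459) passed as lower without glucose. ATF4 (1.02, 0.046) passed there as higher. With quantile normalization the ratio difference of ATF4 (1.65, adjusted p = 0.035) and of RPTOR (-1.43, 0.0469) passed. Input RPKM was lower without glucose too, at 11.1 and 1.995 for LARP1, 2.53 and 0.299 for RPTOR, 2.57 and 0.547 for MTOR and 1.14 and 0.289 for EIF2AK4. Lower IP values alone therefore do not show a lower ratio. The glucose-free input of RPTOR lay below the pseudocount of 1, which understates its rise there, so the negative sign of its difference is uncertain. MYH9 gained most among the mRNAs named, by 3.62 ± 0.79 (limma adjusted p = 0.024), with IP levels of 95.2 in complete and 775 RPKM in glucose-free medium and inputs of 7.84 and 1.77. HIST1H4E, a core histone gene, had a lower ratio without glucose (-2.85 ± 0.40), as did HIST1H2AG (-2.50 ± 0.49). MYH9 also missed the threshold with a pseudocount of 0.1 and with voom. These 3 calls were lost without single libraries: MYH9 without complete input replicate 2, glucose-free input replicate 1 or 2, or glucose-free IP replicate 1 (adjusted p of up to 0.0934), HIST1H4E without glucose-free input replicate 1 or 2 or glucose-free IP replicate 2 (0.0688), and HIST1H2AG without each of the 4 glucose-free libraries (0.1).

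Other large differences were in small RNAs and multicopy genes. SCARNA22 (5.24 ± 0.38) and SNHG9 (3.79 ± 0.46), and the copies RPSAP19 (3.96) and MIR1244-4 (3.73), had higher ratios without glucose in all 8 fits that left out a library. SNHG25 (3.74) and RPL21P16 (3.85) were higher too, and were lost without glucose-free input replicate 1, glucose-free IP replicate 1 or glucose-free IP replicate 2, SNHG25 also without glucose-free input replicate 2 (adjusted p of up to 0.0688 and 0.0688). SCARNA22 had this difference with the IP nearly level, 2.11 and 2.38 RPKM, and the input at 342 in complete and 5.04 in glucose-free medium, and between the IPs alone it stood at -0.19. The mitochondrial tRNAs MT-TF (-6.65) and MT-TP (-6.15) and the U1 RNAs RNU1-1 (-3.88), RNU1-27P (-3.84) and RNU1-3 (-3.80), which are near copies of one another, had lower ratios, as did RPL39P38 (-4.06, but 4.79 between the IPs alone). Each of these 6 was lost without glucose-free input replicate 1 and without glucose-free IP replicate 2. The 3 U1 RNAs were also lost without glucose-free IP replicate 1, and both tRNAs without either complete input, glucose-free input replicate 2 or glucose-free IP replicate 1. MT-TP had the highest adjusted p, 0.124. MT-TS1 (4.32) and MT-TL2 (-4.55) passed with centring but not with scaling (adjusted p = 0.0912 and 0.063), nor without 6 of the 8 single libraries, those but complete input replicate 2 and complete IP replicate 2 for MT-TS1 and those but the complete IPs for MT-TL2 (adjusted p of up to 0.137 and 0.136).

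Histones as a list had lower ratios without glucose, with 10 of 17 lower (15 lower and 1 higher adjusted over the list alone, 6 in both fits), a median of -1.85 and camera adjusted p = 1.94e-05, and adjusted p = 0.904 with an estimated correlation. Oxidative phosphorylation had higher ratios in 15 of 68 (24 adjusted over the list alone, 5 in both fits; median 1.08; camera adjusted p = 3.27e-08, and adjusted p = 0.904 with an estimated correlation), with ATP5ME at 3.03 and ATP5MC1 at 2.77. The scaled fit gave this list a median of 0.62 (camera adjusted p = 0.00782, and 0.974 with an estimated correlation), with 8 higher and 3 lower adjusted over the list alone. After length and GC trends were removed 0.35 was left (adjusted p = 0.0262, and 0.958 with an estimated correlation). Cytosolic ribosomal proteins had a median of 1.21 with 4 of 79 higher (1 adjusted over the list alone, 1 in both fits; camera adjusted p = 1.10e-08, and adjusted p = 0.904 with an estimated correlation), RPS10 being the one past both at 3.17. RPSA (2.13) passed with centring alone, and not without each of the 4 glucose-free libraries (adjusted p of up to 0.151). ATP5ME was lost without each of the 4 glucose-free libraries (adjusted p of up to 0.0743), and ATP5MC1 (0.0683) and RPS10 (0.0577) without glucose-free input replicate 1 or glucose-free IP replicate 2. Mitochondrial ribosomal proteins had a median of 0.43 with 4 of 72 higher (0 adjusted over the list alone, 0 in both fits; camera adjusted p = 0.000398, and adjusted p = 0.904 with an estimated correlation), and limma gave 19 higher at an unadjusted p under 0.05. The scaled fit did not keep this list (adjusted p = 0.801), and its median turned to -0.017 after length and GC trends were removed. Small nucleolar RNAs had 15 lower and 3 higher (20 and 4 adjusted over the list alone, 14 and 2 in both fits; camera adjusted p = 6.59e-05, and adjusted p = 0.904 with an estimated correlation), SNORA54 being listed at 0 in both glucose-free IP libraries. Stress granule and P-body proteins had 5 lower (6 adjusted over the list alone, 1 in both fits; median -0.70; camera adjusted p = 0.00691, and adjusted p = 0.904 with an estimated correlation). CNOT1 was past both fits (-1.67 ± 0.36) but not without each of the 4 glucose-free libraries (adjusted p of up to 0.121). The list did not pass without complete input replicate 1 or complete IP replicate 2 (adjusted p of up to 0.139) nor after length and GC trends were removed (adjusted p = 0.455).

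The interaction gave 508 higher and 983 lower genes with centring, 192 and 265 with scaling and 158 and 213 in both. Higher genes made up 34.1% of calls with centring, 42.0% with scaling and 90.5% with RPKM as deposited (2959 and 311), and 48.6% with quantile normalization. A pseudocount of 0.1 left 73 and 64, and voom on the recovered reads 60 and 63. The counts changed widely in fits that left out 1 library. Those fits too shared 1 spread per gene over the groups, so a library left out could change the SE of other groups. For JUN in complete medium the SE was 0.258 without complete input replicate 2. It was 0.434 without glucose-free input replicate 1, a library outside that comparison, where its change was 3.54. Such counts therefore do not show that the calls rest on a single library. With scaling they ranged from 13 to 1101 higher and from 55 to 1472 lower, lowest without glucose-free input replicate 1 and glucose-free IP replicate 2 and highest without complete IP replicate 1. Each medium is 1 set of libraries and 1 table, so medium and library batch cannot be told apart here or between the inputs. Serum was dialyzed only in the medium lacking glucose, so these cannot be told apart either. The difference also rose with GC content (r = 0.404) and fell with coding length (r = -0.397) across coding genes.

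**Figure D4:**
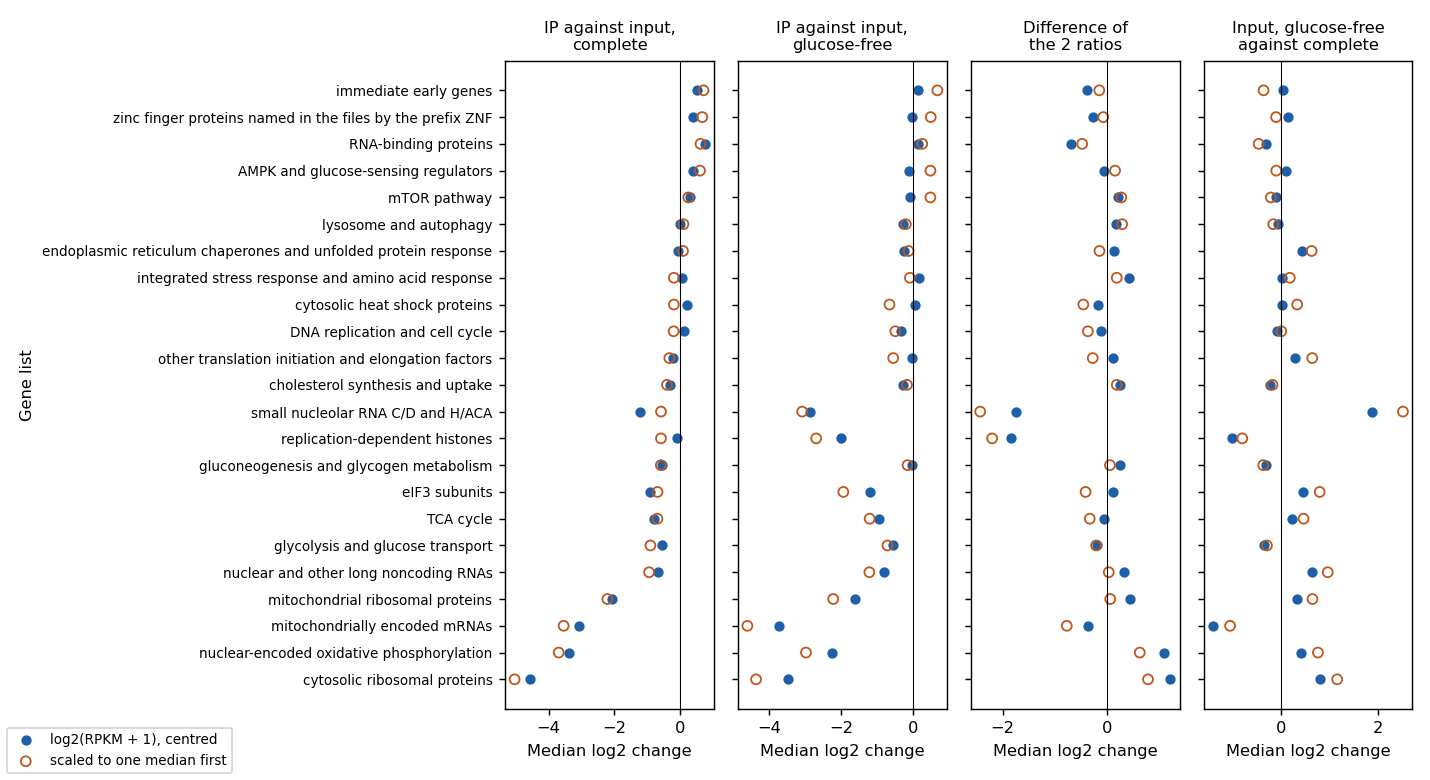
Median log2 change (x axis) of each tested gene list (y axis) in the 4 comparisons, with centred values as filled and values scaled to one median as open points. Cytosolic ribosomal proteins have medians of -4.58 and -3.48 in the IPs, and histones -1.85 in the ratio difference.

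The last comparison was of the inputs, per the labels polyadenylated RNA, of cells without glucose against fed cells. RPL39, a ribosomal protein gene, had 7.85 ± 1.78 RPKM in complete and 2133 ± 37.5 in glucose-free inputs (SD, n = 2), a log2 change of 8.34 ± 0.81 (limma adjusted p = 0.000711), and its copies RPL39P3 (9.65) and RPL39P38 (8.86) rose with it. COX7B (5.42 ± 0.73) and UQCRB (3.77 ± 0.39), parts of respiratory complexes, rose from 1.83 to 80.8 and from 0.847 to 17.9 RPKM. Histone mRNAs fell: HIST1H4C went from 1802 ± 529 to 66.3 ± 0.563 RPKM (-4.30 ± 0.40), and HIST1H1D fell as well (-3.00 ± 0.37). ALDOA, a glycolytic enzyme, fell by 1.93 ± 0.21. LARP1 fell by 1.54 ± 0.29, which was lost without either glucose-free input (adjusted p of up to 0.144).

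RNY1 (7.20), RNU5A-1 (6.83) and the 5S copies RNA5SP226 (6.97) and RNA5SP389 (6.77) rose, and SCARNA22 (-5.42), BCYRN1 (-4.33), RN7SKP230 (-3.71) and VTRNA1-3 (-3.14) fell. Libraries made from poly(A) RNA sample such transcripts only in part. Annotated rRNA took 0.0630% of complete and 1.58% of glucose-free input reads. Whether poly(A) selection was equal was not tested, so these changes and those of histones may not be changes in the cells. MT-TV (6.99) and RPL10P3 (-3.08) were lost without either complete input (adjusted p of up to 0.113 and 0.0568), and HIST1H2AB (-3.43) without complete input replicate 2 (0.0751). JUN (0.30 ± 0.34, adjusted p = 0.601), ATF4 (-0.27 ± 0.36, 0.653), MTOR (-0.75 ± 0.33, 0.18), RPTOR (-0.94 ± 0.27, 0.0578), EIF3D (0.11 ± 0.32, 0.848), EIF2AK4 (-0.30 ± 0.17, 0.278) and BTG1 (0.031 ± 0.22, 0.946) did not pass. In the scaled fit RPTOR (-1.49, adjusted p = 0.00683), MTOR (-1.05, 0.0385) and EIF2AK4 (-0.71, 0.0217) passed as lower without glucose. After the trends were removed RPTOR (-0.72, adjusted p = 0.0284) and BTG1 (-1.20, 0.0117) passed as lower.

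Cytosolic ribosomal proteins rose in 13 of 79 (18 adjusted over the list alone, 13 in both fits; camera adjusted p = 6.64e-07, and adjusted p = 0.743 with an estimated correlation), with RPS13 at 2.91. Mitochondrial ribosomal proteins had 15 higher and 1 lower of 72 (19 and 1 adjusted over the list alone, 15 and 0 in both fits; camera adjusted p = 0.00168, and adjusted p = 0.743 with an estimated correlation). MRPS33 rose by 1.77 but not without complete input replicate 2 or either glucose-free input (adjusted p of up to 0.0931). Oxidative phosphorylation had 13 higher and 3 lower of 68 (14 and 3 adjusted over the list alone, 13 and 2 in both fits; camera adjusted p = 0.0231, and adjusted p = 0.743 with an estimated correlation). Endoplasmic reticulum chaperones had 6 higher of 31 (12 higher and 3 lower adjusted over the list alone, 6 in both fits; camera adjusted p = 0.0182, and adjusted p = 0.743 with an estimated correlation). DERL3, a factor of protein disposal from the reticulum, rose by 1.83 ± 0.19, and SDF2L1 by 2.05 ± 0.45 although it was lost without complete input replicate 2, either glucose-free input or either glucose-free IP (adjusted p of up to 0.135). Long noncoding RNAs rose in 7 of 21 (10 adjusted over the list alone, 7 in both fits; camera adjusted p = 0.00332, and adjusted p = 0.743 with an estimated correlation), with the small nucleolar RNA hosts SNHG8 (3.53), SNHG5 (3.48) and ZFAS1 (2.78). Small nucleolar RNAs had 23 higher and 3 lower of 43 (24 and 3 adjusted over the list alone, 23 and 3 in both fits; camera adjusted p = 1.02e-06, and adjusted p = 0.743 with an estimated correlation). SNORD41 and SNORD46 were listed at 0 in both complete inputs against 15.1 and 17.3 RPKM. Histones fell in 8 of 17 (9 adjusted over the list alone, 6 in both fits; camera adjusted p = 6.64e-07, and adjusted p = 0.743 with an estimated correlation).

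Glycolysis passed downward as a list (camera adjusted p = 0.0268, and adjusted p = 0.743 with an estimated correlation) with 1 higher and 1 lower of 19, the same numbers adjusted over the list alone and in both fits, ALDOA being the one that fell and LDHB (1.65 ± 0.43) the one that rose. The list median of -0.36 became -0.0045 after length and GC trends were removed, 0.11 in the form without coding length. Mitochondrially encoded mRNAs passed downward (camera adjusted p = 0.0124, and adjusted p = 0.743 with an estimated correlation; median -1.42) with 0 members past the threshold in limma, also 0 adjusted over the list alone, and 3 lower at an unadjusted p under 0.05. Stress granule and P-body proteins passed downward (camera adjusted p = 0.0124, and adjusted p = 0.743 with an estimated correlation) with 1 of 25 lower, also 1 adjusted over the list alone, ATXN2L at -1.78 ± 0.33. ATXN2L was lost without either glucose-free input (adjusted p of up to 0.0899), and LDHB without each input and each glucose-free IP (0.228). The scaled fit kept none of these 3 lists (adjusted p = 0.399, 0.249 and 0.078). Without complete input replicate 2 the glycolysis (0.715), oxidative phosphorylation (0.586), endoplasmic reticulum (0.107) and stress granule (0.292) lists did not pass, and without complete input replicate 1 the mitochondrially encoded list did not (0.26), the values in parentheses being adjusted p. Beside these mitochondrial genes, mitochondrial mRNA took 7.54% of reads in the complete and 2.05% in the glucose-free inputs.

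In all, 882 genes were higher and 393 lower in the glucose-free inputs with centring, 1856 and 1677 with scaling, and 882 and 377 in both. Higher genes made up 69.2% of calls with centring, 52.5% with scaling and 28.3% with RPKM as deposited (517 and 1311), and 58.9% with quantile normalization and 53.4% with voom. When 1 library was left out, with 1 spread per gene still shared over the groups, the counts moved. With scaling they ranged from 777 to 2300 higher and from 304 to 2369 lower, lowest without glucose-free input replicate 2 and highest without complete IP replicate 2.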

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

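The tests chosen only after their results were seen were the removal of length and GC trends, including its use for the list differences, the matching on coding length, the interval of the matched median, the olfactory receptor reads and the pseudogene share.

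Ribosomal protein mRNAs were lower, and JUN, LARP1 and RPTOR mRNAs higher, in the IP than in the input. With each library's trend on exon length, coding length and GC removed, the ribosomal protein median was -3.84 in complete and -3.36 in glucose-free medium (upper quartiles -3.03 and -2.78; medians -4.52 and -3.75 in the earlier form of this removal without coding length), which argues against such trends as the whole cause, and JUN stayed at 3.48 and 3.14 (3.17 and 3.03 in the scaled fit before). LARP1 shrank from 2.24 and 2.61 to 1.40 and 1.91 and RPTOR from 1.99 and 1.69 to 1.11 and 0.65, so part of their rise goes with these trends. JUN did not rest on 1 input library, since its highest adjusted p in limma fits without each library was 0.000696 in complete medium. Ribosomal protein mRNAs were also set against other coding genes matched on exon length and input level. This test, with a bound of -1, was written before its result was seen. They lay at a median of -1.77 (95% interval -2.19 to -1.29, quartiles -2.51 and -0.854). The interval comes from the order of the 79 genes, which are not independent replicates. Exon length joins all annotated exons of a gene and can exceed its mRNA, as for RPS21 with 1023 bases against a transcript of 401. Input level was matched only in part, with medians of 428 and 270 RPKM and 52 matched genes. The result argues against joined exon length as the whole cause, but cannot weigh mRNA length or input level. The matched genes themselves had a median of -3.35 against -5.03 for ribosomal protein mRNAs, so most of the fall was shared by the genes matched this way. How much of the fall goes with coding length stays open: against genes of like coding length, a later choice, the median was -1.06 (95% interval -1.21 to -0.683; quartiles -1.47 and -0.356), so the upper quartile missed the bound of -1 set for it, and these matched genes had a median of -4.23. Selective eIF3d binding may account for the pattern, but binding to beads was not tested, as no untagged IP was analysed here.

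Complete IP replicate 2 held more mitochondrial reads than the other IP libraries, and more reads on olfactory receptor genes, which are silent in most cells. These came to 20.4 RPM (95% Poisson interval 18.5 to 22.4) over 381 genes, a signal outside the main comparisons, against 5.06 to 6.05 in the other IP libraries. Some carry-over of DNA may account for this. The inputs held 0.410 to 1.94 RPM, so every IP library lay above every input. A background on silent genes was thus common to the IPs and was not taken out of the IP against input comparisons. The mitochondrial excess over replicate 1 was 14.4 times higher in rRNAs than in mRNAs, which argues against copies of mitochondrial DNA as its whole source. Carry-over of unbound input RNA is argued against by ribosomal protein mRNAs, whose excess as a share of input was -0.00131 times that of MT-RNR2. No biological explanation was tested, since both libraries belong to 1 group.

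Ribosomal protein, respiratory chain and histone lists differed between media, in inputs and IP to input ratios, at camera's preset but not estimated correlation. RPL39 with all its copies differed 465-fold between inputs, and the share of reads on pseudogenes was 1.02 times as high in complete as in glucose-free inputs, which argues against reads moved between RPL39 copies and against multiply placed reads left out of the complete table alone. With length and GC trends removed the histone ratio difference stayed at -1.96 (camera adjusted p = 7.6e-10, and 0.958 with an estimated correlation). That argues against these trends, as fitted, as its whole cause. The same removal moved the histone median from -0.58 to 1.62 in the complete IP and from -2.69 to -0.47 in the glucose-free IP. The test is weak, as it depends on how well the trends fit these genes. The differences of ribosomal proteins, 0.49, and of oxidative phosphorylation, 0.35, lay between the bounds of 0.3 and 0.5 and stay open (0.66 and 0.54 in the earlier form of the removal). The histone and ribosomal protein tests were first a joint test, which was undecided, and were parted after its value was seen. A GC bias between tables also stays open, since the change correlated with GC content at r = -0.294 in the inputs and 0.135 in the IPs. Glucose deprivation, the difference the design names, cannot be told apart from library batch or dialyzed serum. It was not tested separately, and the wording of this pattern was widened after its values were seen.

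Results whose IP to input ratio differed between media by the interaction term, among the named protein-coding genes past the threshold in both fits and lists past it with centring, are given here as values. Single mRNAs were MYH9 (3.62), RPS10 (3.17), ATP5ME (3.03), ATP5MC1 (2.77), HIST1H2BC (-1.60), HIST1H4E (-2.85), HIST1H2AG (-2.50) and CNOT1 (-1.67), in log2. List medians, with those of the scaled fit in parentheses, were 1.21 (0.78) for cytosolic ribosomal proteins, 0.43 (0.058) for mitochondrial ribosomal proteins, 1.08 (0.62) for oxidative phosphorylation, -1.85 (-2.20) for histones, -1.74 (-2.43) for small nucleolar RNAs and -0.70 (-0.48) for stress granule and P-body proteins. The scaled fit did not keep the mitochondrial ribosomal protein list (adjusted p = 0.801). With an estimated correlation 0 of these lists passed in limma's camera (adjusted p = 0.904), 0 had an unadjusted p under 0.05, and fry called 0.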

How the results depend on the processing

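Alternatives chosen after the data were seen are named with the processing above, and all others were planned. In both IP against input comparisons the named genes mostly kept their direction and side of the threshold: of 53 called in complete medium 41 passed in all 8 fits without 1 library, and of 59 without glucose 45. The ratio difference kept 7 of 40 and the inputs 24 of 45. Called lists passed all 8 in 6 of 9, 9 of 10, 5 of 6 and 5 of 10 cases in the same order. A group left with 1 library was assumed to vary like the other groups. Planned but not run were a sum over transcripts, since the tables list genes, and a test of whole counts, since the tables hold RPKM. Depth limits the glucose-free IPs most, at 8656923 and 12034189 reads, where 3 reads equal 0.346 and 0.249 RPM.

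With centring, counts without 1 library ranged from 1842 to 2882 higher (complete IP), 2878 to 3580 lower (complete IP), 1049 to 2247 higher (glucose-free IP), 2343 to 4520 lower (glucose-free IP), 12 to 1660 higher (ratio difference), 30 to 2335 lower (ratio difference), 344 to 1680 higher (input), 54 to 1004 lower (input). With scaling, counts without 1 library ranged from 2460 to 3146 higher (complete IP), 2793 to 3094 lower (complete IP), 1860 to 3286 higher (glucose-free IP), 2506 to 3528 lower (glucose-free IP), 13 to 1101 higher (ratio difference), 55 to 1472 lower (ratio difference), 777 to 2300 higher (input), 304 to 2369 lower (input). Called lists ranged from 7 to 10 (complete IP), 9 to 10 (glucose-free IP), 6 to 9 (ratio difference), 8 to 13 (input). Replicate 2 ratios alone gave a correlation between media of r = 0.656 and rho = 0.586; rho was 0.838 with a mean RPKM of at least 5, 0.816 with scaling and 0.823 with all trends removed.

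With RPKM as deposited, there were 6426 higher and 1245 lower in the complete IP, 8250 higher and 554 lower in the glucose-free IP, 2959 higher and 311 lower in the ratio difference, 517 higher and 1311 lower in the input. With quantile normalization, there were 2382 lower in the glucose-free IP, 723 lower in the input. With a pseudocount of 0.1, there were 73 higher and 64 lower in the ratio difference, 1519 higher and 1427 lower in the input. With no filter, there were 8392 higher and 12607 lower in the complete IP, 11352 higher and 10210 lower in the glucose-free IP, 893 higher and 150 lower in the ratio difference, 407 higher and 219 lower in the input. With a mean RPKM of at least 5, there were 1364 higher and 1533 lower in the complete IP, 1451 lower in the glucose-free IP, 147 higher and 191 lower in the ratio difference, 463 higher in the input. With an absolute log2 change of at least 1, there were 1410 higher in the complete IP, 1194 higher and 2400 lower in the glucose-free IP. With only the libraries compared, there were 1538 higher in the complete IP, 2794 higher in the glucose-free IP, 639 lower in the input. With the IP libraries alone, there were 2629 higher and 2380 lower in the ratio difference. With scaling, there were 2825 higher in the glucose-free IP, 192 higher and 265 lower in the ratio difference, 1856 higher and 1677 lower in the input. With voom, there were 2866 higher in the glucose-free IP, 60 higher and 63 lower in the ratio difference, 2021 higher and 1761 lower in the input. With all trends removed, there were 2486 lower in the glucose-free IP, 276 higher and 243 lower in the ratio difference, 1613 higher and 1637 lower in the input. With exon length and GC trends removed, there were 2208 lower in the complete IP, 2245 lower in the glucose-free IP, 244 higher and 186 lower in the ratio difference, 1504 higher and 1597 lower in the input. Fewer genes were tested with the stricter filter and the trend removals, and a fold threshold can only lower a count; for the others the cause was not tested.

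With an estimated correlation 0 gene lists passed in each comparison, centred or scaled, where 1, 1, 0 and 0 had an unadjusted p under 0.05 with centring. Fry called 11 lists in the complete IP, 8 in the glucose-free IP, 0 in the ratio difference and 4 in the input. Of these, camera did not call eIF3 subunits (downward in both IPs, upward in the input) or AMPK regulators (upward in both IPs). It also did not call cholesterol synthesis or lysosome and autophagy, both downward in the complete IP. Fry did not call mitochondrially encoded mRNAs and immediate early genes in the IPs, nor the integrated stress response and ZNF genes in the glucose-free IP. A mean RPKM of at least 5 left 5 called in the complete IP, and either trend removal left 3 in the ratio difference. With an estimated correlation after all trends were removed, mitochondrial ribosomal proteins passed in both IPs (adjusted p = 0.0272 and 0.029). All other lists with all trends removed, and all lists with scaling, missed the threshold at an estimated correlation.

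Single lists changed sides of the threshold at the preset correlation, given here with adjusted p. First come those with scaling. In the glucose-free IP gained lists were eIF3 subunits downward 0.00502. In the input gained lists were eIF3 subunits upward 0.0049, TCA cycle upward 0.013. In the glucose-free IP lost lists were integrated stress response 0.835. In the ratio difference lost lists were mitochondrial ribosomal proteins 0.801. In the input lost lists were glycolysis 0.399, mitochondrially encoded mRNAs 0.249, stress granule and P-body proteins 0.078. The next are with all trends removed, over coding genes alone. In the complete IP gained lists were eIF3 subunits downward 0.00721, glycolysis downward 0.0039, gluconeogenesis downward 0.00909, histones upward 0.000719. In the glucose-free IP gained lists were eIF3 subunits downward 0.000767, glycolysis downward 0.0035. In the input gained lists were eIF3 subunits upward 0.000721, other translation factors upward 0.0248, TCA cycle upward 0.0165, immediate early genes downward 0.0344. In the complete IP lost lists were stress granule and P-body proteins 0.956. In the glucose-free IP lost lists were integrated stress response 0.75, histones 0.161. In the ratio difference lost lists were mitochondrial ribosomal proteins 0.677, stress granule and P-body proteins 0.455. In the input lost lists were glycolysis 0.893, stress granule and P-body proteins 0.0909. The last are with exon length and GC trends removed. In the complete IP gained lists were eIF3 subunits 0.0112, glycolysis 0.00827, histones 0.00627. In the glucose-free IP gained lists were eIF3 subunits 0.000673, glycolysis 0.00402. In the input gained lists were eIF3 subunits 0.000737, other translation factors 0.0285, TCA cycle 0.00884. In the complete IP lost lists were stress granule and P-body proteins 0.925. In the glucose-free IP lost lists were integrated stress response 0.766, histones 0.149. In the ratio difference lost lists were mitochondrial ribosomal proteins 0.848, stress granule and P-body proteins 0.363. In the input lost lists were glycolysis 0.893, stress granule and P-body proteins 0.0998.

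Turned signs are given where the main fit or the alternative passed the threshold, and for lists where the test changed direction. With RPKM as deposited, signs turned for BTG1 1.01, MRPS26 0.38, MRPS5 0.33, IDH3A 0.64, DLD 0.57, ATP5F1A 0.48 (complete IP), EIF2AK4 1.51, BTG1 1.92, RPL4 0.92, RPL5 0.72, MRPS5 1.34, MRPL45 1.27, SARS 0.76, SDHC 1.12, SDHD 1.05, ATP5F1A 0.85, UQCRFS1 0.80, KLF10 0.76, FOSL1 0.83, HIST1H2BJ 0.84, HIST2H2BE 0.77, SNORD99 0.82, SNORD83A 0.44, ZNF239 0.30 (glucose-free IP); past the threshold were BTG1, IDH3A, DLD (complete IP), EIF2AK4, BTG1, RPL4, MRPS5, MRPL45, SDHC, SDHD, ATP5F1A, UQCRFS1, KLF10, FOSL1, SNORD99 (glucose-free IP). With quantile normalization, signs turned for RPL4 0.13, MRPS26 0.45 (complete IP), RPL4 1.59, RPL5 1.49, EIF4EBP1 0.12, MT-ND6 0.59 (glucose-free IP); past the threshold were RPL4, RPL5 (glucose-free IP). With a pseudocount of 0.1, signs turned for BTG1 0.98 (glucose-free IP); past the threshold were BTG1 (glucose-free IP). With no filter, signs turned for BTG1 0.84, MRPS26 0.21, MRPS5 0.16, IDH3A 0.47, DLD 0.41, ATP5F1A 0.31 (complete IP), EIF2AK4 1.40, BTG1 1.81, RPL4 0.81, RPL5 0.61, MRPS5 1.23, MRPL45 1.16, SARS 0.65, SDHC 1.01, SDHD 0.94, ATP5F1A 0.74, UQCRFS1 0.69, KLF10 0.65, FOSL1 0.72, HIST1H2BJ 0.73, HIST2H2BE 0.66, SNORD99 0.71, SNORD83A 0.33, ZNF239 0.19 (glucose-free IP); past the threshold were BTG1 (complete IP), EIF2AK4, BTG1, MRPS5, MRPL45, SDHC, SDHD, UQCRFS1, FOSL1 (glucose-free IP). With the IP libraries alone, signs turned for SCARNA22 -0.19, RPL39P38 4.79, LARP1 -1.10, SNORA11F -0.67 (ratio difference); past the threshold were RPL39P38, LARP1 (ratio difference). With scaling, signs turned for BTG1 0.76, FOSL1 0.16 (glucose-free IP); past the threshold were BTG1 (glucose-free IP). With voom, signs turned for BTG1 1.35, FOSL1 0.41 (glucose-free IP); past the threshold were BTG1 (glucose-free IP). With all trends removed, signs turned for stress granule and P-body list -0.081, EIF2AK4 -0.86, BTG1 0.87, MTOR -0.11, MRPS26 0.61, AGO1 -0.16 (complete IP), EIF3D -0.68, BTG1 1.62, SDHD 0.57, KLF10 0.013, FOSL1 1.09, HIST1H2BJ 0.49 (glucose-free IP), mitochondrial ribosomal protein list -0.017, ATXN2 0.057 (ratio difference), glycolysis list -0.0045, BTG1 -1.20 (input); past the threshold were EIF2AK4, BTG1 (complete IP), EIF3D, BTG1, SDHD, FOSL1 (glucose-free IP), BTG1 (input). With exon length and GC trends removed, signs turned for EIF2AK4 -0.54, MRPS26 0.73, AGO1 -0.36 (complete IP), BTG1 1.18, MRPL45 0.27, SDHD 0.25, KLF10 0.16, FOSL1 1.19, HIST1H2BJ 0.47 (glucose-free IP), ATXN2 0.054 (ratio difference), glycolysis list 0.11, BTG1 -1.03 (input); past the threshold were EIF2AK4, MRPS26 (complete IP), BTG1, FOSL1 (glucose-free IP), BTG1 (input). With neither past the threshold, signs also turned in at least 1 alternative or leave-out for ATF4, BTG1 (complete IP), EIF3D, EIF2AK4, BTG1, MTOR (glucose-free IP), EIF2AK4, BTG1, RPTOR, LARP1, JUN (ratio difference), EIF3D, ATF4, BTG1, JUN (input). List medians turned in at least 1 alternative, though the direction of the test did not, for TCA cycle (complete IP), mitochondrial ribosomal proteins, integrated stress response, TCA cycle, ZNF genes (glucose-free IP), stress granule and P-body proteins (ratio difference), mitochondrial ribosomal proteins (input). Calls of genes named in the main text also ended in alternatives. Complete IP calls that ended were EIF3D (with only the libraries compared); EIF3D, MTOR, CNOT1, TNRC6B (with all trends removed); MTOR, TNRC6B (with exon length and GC trends removed); RPL4 (with RPKM as deposited); RPL4, MT-ATP8 (with quantile normalization). Glucose-free IP calls that ended were ATF4 (with a pseudocount of 0.1); ATF4 (with scaling); ATF4 (with voom); RPL4, IDH3G, ZNF581, ZNF239 (with no filter); IDH3G, ZNF581, ZNF239 (with RPKM as deposited); HIST1H4C, ZNF239 (with exon length and GC trends removed); ZNF581 (with quantile normalization). Ratio difference calls that ended were SCARNA22, MT-TP, SNORA80B, SNORA11F, SNORD41 (with the IP libraries alone); MT-TS1, MIR1244-4, MYH9, MT-TF, MT-TP, MT-TL2, RPL39P38, RPSA, MRPL52, HIST1H2BC, SNORA80B, SNORA11F, TNRC6B, CNOT1 (with a pseudocount of 0.1); MT-TS1, MT-TF, MT-TP, MT-TL2, RNU1-1, RNU1-27P, RNU1-3, HIST1H2BC, HIST1H4E, HIST1H2AG, TNRC6B, CNOT1 (with no filter); MT-TS1, RPSA, MRPL52, SNORA11F (with a mean RPKM of at least 5); MT-TS1, MT-TF, MT-TP, HIST1H2BC, SNORA11F (with the replicate block); MT-TS1, MT-TL2, RPSA, MRPL52, SNORA11F, TNRC6B (with scaling); MT-TS1, SNHG25, MIR1244-4, MYH9, MT-TF, MT-TP, MT-TL2, RPSA, MRPL52, SNORA80B, SNORA11F, TNRC6B, CNOT1 (with voom); MT-TP, MT-TL2, RPL39P38 (with quantile normalization); RPSA, MRPL52, TNRC6B (with all trends removed); RPSA, MRPL52, HIST1H2BC, TNRC6B (with exon length and GC trends removed); HIST1H2BC, CNOT1 (with RPKM as deposited); SNORA11F (with no intensity trend). Input calls that ended were MT-TV, LARP1, MRPS33, SDF2L1, LDHB, ATP5MC1, ATXN2L (with no filter); VTRNA1-3, ATP5MC1, SNORA80B (with a pseudocount of 0.1); SDF2L1, LDHB (with quantile normalization); LDHB (with RPKM as deposited); ATP5MC1 (with only the libraries compared); ATP5MC1 (with the replicate block); ATP5MC1 (with scaling); ATP5MC1 (with voom). The cause was not tested, except that with RPKM as deposited or no filter the median shift stays in or is set over other genes.

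The replicate numbers were checked for pairing: differences between replicates 1 and 2 of input and IP correlated across genes at -0.0067 in complete and 0.139 in glucose-free medium, over only 2 pairs, so the numbers were not taken to pair libraries. With the replicate block the counts higher and lower were 2312 and 3270 (complete IP) and 1787 and 3597 (glucose-free IP). They were 425 and 684 (ratio difference, 75 and 133 in the scaled fit) and 786 and 328 (input).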

Other observations

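Genes in this part were picked from the fixed lists after their values were seen. The mRNAs of eIF3 itself parted: EIF3A, the largest subunit, was higher in the IP in complete and glucose-free medium (2.82 and 2.57), while EIF3I (-3.00 and -2.33), EIF3K (-3.09 and -1.63), EIF3F (-2.47 and -1.41), EIF3H (-2.15 and -2.14), EIF3G (-1.77 and -1.83) and EIF3L (-1.56 and -1.21) were lower. The 13 subunits had 2 higher and 6 lower of 13 in the complete IP (adjusted p = 0.275) and 1 and 7 in the glucose-free IP (0.368). The list passed downward in the glucose-free IP in the scaled fit (adjusted p = 0.00502, 9 lower, median -1.94), where the complete IP had 0.0678, and in both IPs after length and GC trends were removed (0.00721 and 0.000767). With an estimated correlation it passed in none of these (adjusted p = 0.414, 0.365 and 0.252). With fry the list passed downward in both IPs with centring (adjusted p = 0.00132 and 0.00214). Between the inputs it passed upward in the scaled fit (0.0049, and 0.814 with an estimated correlation) and not in the centred one (0.0586); between the inputs EIF3E (3.23) and EIF3M (2.16) were higher without glucose. Among other translation factors the cap-complex scaffold EIF4G1 (2.56 and 2.98), EIF4G2 (2.22 and 1.85) and PABPC4 (1.63 and 1.75) were higher in the IPs and EEF1B2 (-2.88 and -2.88), EIF6 (-2.84 and -2.16) and EIF4E2 (-1.81 and -1.94) lower. That list had 5 higher and 9 lower of 27 in the complete IP (adjusted p = 0.867) and 12 and 11 in the glucose-free IP (0.464). The long noncoding RNAs NORAD (2.60 and 3.20) and TUG1 (1.34 and 1.09) were higher and SNHG8 (-3.13 and -2.51) and GAS5 (-3.30 and -2.28) lower, in a list that did not pass in the IPs (adjusted p = 0.522 and 0.784). Of the casein kinase 2 genes, CSNK2B was lower in the complete IP (-1.81 ± 0.32), and CSNK2A2 passed with centring alone (0.71 and 0.92).

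Metabolic genes went both ways in the IPs. The glucose-phosphorylating enzyme HK2 (1.70 and 1.20) and PFKFB3 (1.65 and 1.20) were higher, GAPDH (-2.88 and -3.18), TPI1 (-2.47 and -1.15) and PGAM1 (-1.52 and -1.39) lower, and glycolysis did not pass as a list with centring (adjusted p = 0.531 and 0.84) or scaling (0.113 and 0.129). After length and GC trends were removed it passed downward in both IPs (medians -1.05 and -1.34, adjusted p = 0.0039 and 0.0035), but not with an estimated correlation (0.44 and 0.631). The AMPK kinase STK11 (1.70 and 2.92), the glucose-sensing factor MLXIP (2.17 and 2.43) and the autophagy kinase ULK1 (1.32 and 2.20) were higher, and the lysosomal mTORC1 anchors LAMTOR4 (-3.53 and -1.74) and LAMTOR2 (-3.24 and -1.95) lower. The AMPK list had 5 higher and 3 lower of 12 in the complete IP (adjusted p = 0.279) and 4 and 4 in the glucose-free IP (0.368). With fry it passed upward in both (adjusted p = 0.0031 and 0.00529). The mTOR list had 11 higher and 10 lower of 30 in the complete IP (adjusted p = 0.529) and 9 and 10 in the glucose-free IP (0.3). Gluconeogenesis had 1 higher and 5 lower of 12 in the complete IP (adjusted p = 0.489) and 2 and 3 in the glucose-free IP (0.776), and lysosome and autophagy had 6 higher and 13 lower of 36 in the complete IP (adjusted p = 0.891) and 8 and 10 in the glucose-free IP (0.485). Gluconeogenesis passed downward in the complete IP after all trends were removed (adjusted p = 0.00909), but not with an estimated correlation (0.399) or in the earlier form of that removal (0.053). Heat shock proteins had 2 higher and 3 lower of 17 in the complete IP (adjusted p = 0.636) and 2 and 2 in the glucose-free IP (0.368), and DNA replication and cell cycle had 10 higher and 9 lower of 45 in the complete IP (adjusted p = 0.636) and 6 and 13 in the glucose-free IP (0.776). Cholesterol synthesis had 2 higher and 9 lower of 22 in the complete IP (adjusted p = 0.53) and 5 and 6 in the glucose-free IP (0.485); between the inputs it had 1 higher, ACAT2 (1.10), and 5 lower without glucose, among them SCD (-2.20), DHCR7 (-1.10), INSIG1 (-1.09) and SREBF2 (-0.98), and the list did not pass (adjusted p = 0.0586). In lists that did not pass, median, mean and test differed in sign in the glucose-free IP for other translation factors, mTOR, AMPK, endoplasmic reticulum chaperones, gluconeogenesis, cholesterol synthesis, DNA replication, and lysosome and autophagy. They also differed in the complete IP for mTOR and endoplasmic reticulum chaperones, in the ratio difference for glycolysis and heat shock proteins, and between inputs for the integrated stress response, heat shock proteins and immediate early genes.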
